A study of Mus musculus with 4 samples.

How the data were processed

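Dorsal root ganglia of C57BL/6 mice were sampled at E16 and in the adult, and chromatin from sonicated nuclei was immunoprecipitated with an antibody against MEIS1, MEIS2 and MEIS3, per the labels' protocols. Labels give the cell type as sensory neurons, but a ganglion also holds glia, fibroblasts, vessels and immune cells, and no sorting step is named. Each of the 4 groups (E16 and adult, immunoprecipitated and input) held 1 library. Libraries were made with an Illumina ChIP kit, per the labels' protocols, and reads were handled with bcl2fastq 2.17 and FastQC and placed on mm10, per the submitters' processing notes. The aligner, the handling of duplicate reads and multiply mapped reads, and the callers' settings were not given in the sources used here. Reads placed in more than one copy of a repeat, and duplicates that were kept or dropped, can change fragment numbers and folds.

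Peaks were called with MACS2 2.1.1 and with MACS 1.4.2, per the submitters' processing notes, on the immunoprecipitated library of each age against the input of that age, per the labels. The MACS2 lists deposited by the authors give for each peak its position, summit, score, fold enrichment over the local background, and −log10 p and −log10 q values. The MACS 1.4 lists deposited by the authors give positions and a score, which is the −log10 of the p-value times 10. Every peak lay on an assembled chromosome, and no column was left out. The MACS2 lists were used throughout, and the MACS 1.4 lists as the alternative caller, with the middle of a MACS 1.4 peak standing for its summit. Because peaks were called separately at each age, a peak missing at one age can be a site just below the caller's threshold.

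Depth was not given in the sources used here and was worked out from the lists. In MACS2 a fold is (fragments at the summit + 1) / (local background + 1) and the p-value is the Poisson probability of more fragments than at the summit given that background, so both numbers were sought from a fold and a p-value together, taking the whole number of fragments with the smallest error in −log10 p. Whole numbers within a tolerance of 0.001 were found for all peaks of both lists (largest error 0.000171). For 1 E16 peak a second whole number was also within that tolerance (error 0.000718). The genome-wide background of a list was taken as its smallest local background, which 229 E16 and 114 adult peaks had to within 0.1%. Fragment length and total fragment numbers were not given in the sources used here, so only the ratio of these backgrounds, 3.55, was used for depth. Where the scaled input sets the background, this number follows both libraries.

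Peaks were shared where they overlapped by at least 1 bp. A peak was clustered where another peak of its list lay within 10000 bp, and isolated otherwise. Random placement put each peak, with its width, at a uniform position on its own chromosome between the first and the last annotated gene, in 1000 draws with a fixed seed. Assembly gaps and sequence that short reads cannot reach were not excluded, so random overlap counts are somewhat too low. Random shares inside genes may be too low as well. The fold of shared and unshared peaks was compared by permuting the shared status over the peaks of a list 100000 times. Shares of peaks have exact (Clopper-Pearson) 95% intervals and fragment numbers exact Poisson 95% intervals.

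Genes came from a table of the GRCm38.p6 assembly, whose chromosome coordinates are those of mm10, with 49603 genes on assembled chromosomes, of which 21779 were protein-coding. The table has gene starts and ends but no strand, exons or sequence. The planned split into promoter, exon, intron and intergenic sequence was therefore replaced by summits inside a gene, within 1000 bp of either gene boundary, and more than 100000 bp from any gene, and distance to the nearest gene replaced distance to the nearest transcription start. The planned motif comparison and the alternatives that need soft-masked sequence were not run. Whether a summit lay in an exon, an intron or an untranslated region was not analysed here.

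The design, the alternatives, 12 gene lists of 408 genes and the rule for named genes were fixed before the data were examined. The rule named, per age, the nearest protein-coding genes of the 12 peaks of highest fold, up to 4 members of each list with the highest folds, the genes of the 10 shared sites with the highest mean fold, up to 8 protein-coding genes with a summit within 1000 bp of a boundary, and Meis1, Meis2 and Meis3. Gabrb1, Grik4, Gm8882, Thsd7a, Parp11, Chl1, Cdh11, Tcte2, Smo, Cdc23, Cdc27 and Rn18s-rs5 were named after their values were seen. All 408 list genes were found in the gene table. A list member counted as hit where a summit lay in its body or within 10000 bp, random placements gave a one-sided empirical p, and Benjamini-Hochberg adjustment covered 24 tests.

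Alternatives were the other caller, stricter lists (−log10 q of at least 3, or a fold of at least the list's median), other overlap rules, protein-coding genes only, 5000 bp for 1000 bp at gene boundaries, 50000 bp for 10000 bp around list genes, and isolated peaks only. A background of peaks moved by 50000 to 500000 bp was added after the data were seen, as were isolated peaks for location, lists, callers and fold. Moved positions were not kept inside the assembled sequence. The steps were tested on simulated data. Of 40 overlaps planted among 419 peaks, 40 were found. Fragment numbers were recovered for 389 of 389 simulated peaks, whereas folds and p-values drawn independently gave whole numbers for 3 of 300. Of 419 simulated summits, the 251 placed inside genes were found there. A gene list with 20 planted hits among 419 peaks was returned with 21, against at most 9 in random placements, and 0 other lists passed. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.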

Results

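Binding of MEIS proteins to DNA was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mouse dorsal root ganglia, the clusters of sensory neurons beside the spinal cord, at embryonic day 16 (E16) and in the adult. MEIS1, MEIS2 and MEIS3 are homeodomain transcription factors of the TALE class, and the antibody was labelled as recognising all of them, while the series title names Meis2. Of the 4 libraries, 1 at each age was immunoprecipitated and 1 at each age was input DNA, taken without immunoprecipitation. Each peak list came from 1 immunoprecipitated library set against the input of its own age. There was thus no replicate check at either age, no p-value was computed between the ages, and all intervals cover counting error only. Coordinates are those of mm10. The fold enrichment of a peak over its local background is the authors' own value from MACS2, and it ranks peaks only within its list.

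Of the 12 adult peaks of highest fold enrichment, 3 lay inside a protein-coding gene and the other 9 lay 47.4 to 937 kb from the nearest one. The first was at chromosome 17, 4626048 to 4626710, 368 kb from Arid1b, which encodes a subunit of the BAF chromatin remodelling complex, with a fold of 152.51. It was followed by a peak 927 kb from Bcl11a, a zinc-finger transcriptional repressor (chromosome 11, 25099970 to 25100319, fold 54.3). The next lay 125 kb from Pou4f1, which encodes the sensory neuron transcription factor BRN3A (chromosome 14, 104336840 to 104337149, fold 49.2). In the E16 list the first was at chromosome 2, 98666122 to 98667425 (fold 22.4), 1035 kb from Lrrc4c, a netrin-G ligand, and the second was the site near Arid1b (4626191 to 4626693, fold 19.6). A peak 47.4 kb from Sulf1, an extracellular heparan sulfate endosulfatase, was among the 12 highest at both ages, with a fold of 16.97 at E16 and 28.8 in the adult.

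Others of the 12 highest adult peaks lay 69.2 kb from the integrin gene Itga11 (fold 36.4) and inside Ano2, a calcium-activated chloride channel gene (chromosome 6, 125876810 to 125877287, fold 36.3). A further peak lay 125 kb from Marcks, which encodes an actin-binding substrate of protein kinase C (fold 32.9). Peaks near the claudin family gene Cldn34c1 (fold 30.7), Nxph1, which encodes a neurexin ligand (fold 29.8), and the sialyltransferase gene St6galnac3 (fold 27.1) came next. The last of the 12 were inside Plxdc2, a plexin domain gene (fold 26.6), and the hepatic lipase gene Lipc (fold 26.3). At E16 the remaining places among the 12 highest were another peak of the chromosome 2 array nearest to Lrrc4c (fold 18.4) and a peak 29.4 kb from Rpusd4, a mitochondrial pseudouridine synthase gene (fold 16.6). They also included 6 peaks in a single array on chromosome 9 whose nearest gene was Alkbh8, a tRNA methyltransferase gene (folds 12.1 to 15.2), and a peak 116 kb from Gm2244 (fold 12.2).

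MACS2 listed 419 peaks at E16 and 375 in the adult. The median fold was 5.69 at E16 (quartiles 4.92 and 6.51) and 5.78 in the adult (quartiles 5.38 and 7.85), and 24 E16 peaks and 63 adult peaks had a fold above 10. The median width of peaks was 175 bp at E16 and 168 bp in the adult. The narrowest width of the list was held by 258 E16 peaks (175 bp) and 161 adult peaks (163 bp). With so many peaks at the lower end, widths say little about the size of the sites. The fold and p-value of each peak together gave whole numbers of fragments at the summit for all 419 and all 375 peaks, within 0.001 on the −log10 p scale. The median peak rested on 7 fragments at E16 (range 4 to 254) and 6 in the adult (range 3 to 202). The genome-wide background was 0.230 fragments per base at E16 and 0.0647 in the adult, a ratio of 3.55. A peak with 7 fragments has an exact Poisson 95% interval of 2.81 to 14.4 fragments, so most single peaks were measured with low precision.

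Peaks at the same sites occurred in both lists more often than random placement gave. Of the E16 peaks, 46 overlapped an adult peak by at least 1 bp. Among those away from dense arrays, the sites with the highest mean fold were those near Arid1b, Bcl11a, Pou4f1, Sulf1 and Nxph1 and inside Plxdc2. At the site near Arid1b the summit held 24 fragments at E16 (95% interval 15.4 to 35.7) and 173 in the adult (148 to 200.8), with no scaling for depth. At the site near Pou4f1 it held 11 (5.49 to 19.7) and 69 (53.7 to 87.3), and near Bcl11a 9 (4.12 to 17.1) and 61 (46.7 to 78.4). Near Sulf1 it held 26 (16.98 to 38.1) and 44 (32.0 to 59.1). Over the genome-wide background of each list these were 113 and 680 times near Sulf1 and 105 and 2674 times near Arid1b, at E16 and in the adult. Summits of the sites near Arid1b, Bcl11a, Pou4f1 and Sulf1 were 3 to 6 bp apart between the ages.

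The 46 shared E16 peaks made up 11.0% of the list (exact 95% interval 8.15 to 14.4), and 54 adult peaks, 14.4% of that list (11.0 to 18.4), overlapped an E16 peak. In 1000 random placements on the same chromosomes, at most 1 E16 peak and at most 2 adult peaks overlapped, which gave an empirical one-sided p of 0.000999 at each age, the smallest that 1000 draws can give. Without peaks that had a neighbour of their own list within 10000 bp, 20 of 370 E16 peaks (5.41%) and 20 of 340 adult peaks (5.88%) were shared, against at most 1 and 2 in random placements. These overlapped an isolated peak of the other age. With overlaps of clustered peaks of the other age counted too, 21 and 22 isolated peaks were shared. The remaining 373 E16 and 321 adult peaks had no MACS2 peak at the other age, but 1 library at each age, of unequal depth, does not show that a site was unoccupied there.

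**Figure D1:**
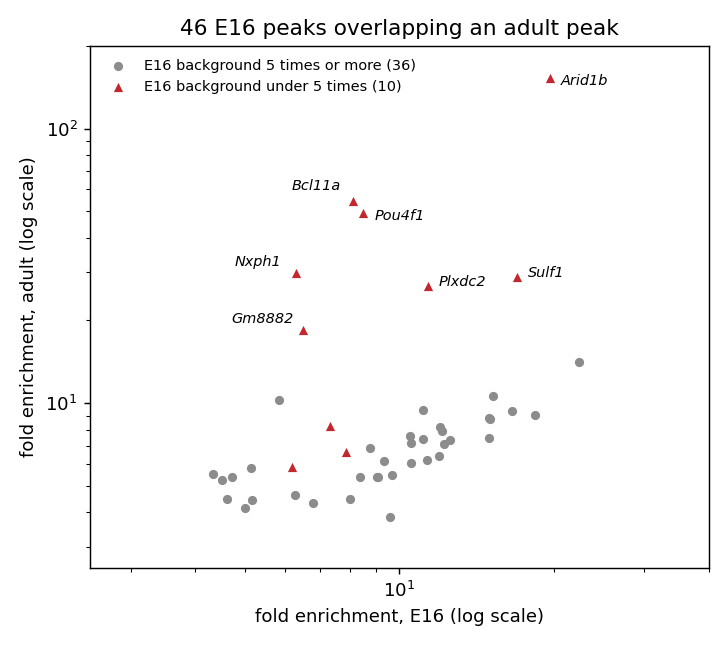
Fold enrichment (authors' values, log axes) of the 46 E16 peaks that overlap an adult peak, with the E16 value on the horizontal axis and the adult value on the vertical axis. Red triangles mark the 10 sites with an E16 local background under 5 times the genome-wide value (nearest gene named at 7, with the site near Arid1b at 19.6 and 152.51), grey circles mark the other 36, and each axis has its own list's scale.

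Shared sites fell into 2 kinds by their E16 local background, the fragment number that the caller took as the local reference. At 10 shared sites, all isolated, the E16 local background was at most 2.57 times the genome-wide value: those near Arid1b, Bcl11a, Pou4f1, Sulf1, Nxph1, Gm8882, Thsd7a and Parp11 and those inside Plxdc2 and Lrp1b, which encodes a receptor of the LDL receptor family. They were chosen by E16 background alone, and their adult local background ran from 2.18 to 10.9 times the genome-wide value. Of 321 unshared adult peaks, 85 reached the lowest of these values, and the median of the unshared was 1.09 times. The adult background was thus raised at these sites too. It was 5 times or more at 4 of them, those near Pou4f1 (6.53) and Sulf1 (8.71) and inside Plxdc2 (5.45) and Lrp1b (10.9). The median fold of the 10 was 7.995 in the E16 list and 27.7 in the adult list. At the other 36 the E16 local background was at least 6.73 times and the adult one at least 7.62 times the genome-wide value, and the median fold was 10.1 in the E16 list and 6.31 in the adult list. These 36 included the site 29.4 kb from Rpusd4, with 254 fragments at E16 and 202 in the adult, and a site inside Chl1, a neural cell adhesion gene (chromosome 6, 103648947 to 103649364), with 83 and 56. The limit of 5 times the genome-wide background was chosen after the values were seen.

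Dense arrays held a large part of the shared peaks. On chromosome 9, 26 E16 peaks lay between 2999896 and 3038356, where the assembled sequence of that chromosome begins, and 17 of them were shared. In the adult, 22 peaks lay between 2999961 and 3036475, and all 22 were shared. Their median local background was 18.8 times the genome-wide value at E16 and 67.5 times in the adult. The array on chromosome 2, 98662167 to 98667425, held 4 peaks at each age, all shared, with local backgrounds of 45.4 and 206 times. On chromosome 17, 3 E16 and 2 adult peaks overlapped Rn18s-rs5, a gene annotated as related to 18S ribosomal RNA (39846354 to 39848202), with folds of 4.52 to 5.63 and 5.22 to 5.81. Arrays of at least 3 peaks without a shared peak were found at E16 near Tcte2 on chromosome 17 (4 peaks, highest fold 11.9) and near Smo on chromosome 6 (3 peaks, highest fold 7.43), and in the adult at Cdc27 on chromosome 11 (3 peaks, highest fold 11.3). Counting clusters of 2 or more peaks, 49 E16 peaks formed 9 and 35 adult peaks formed 5.

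**Figure D2:**
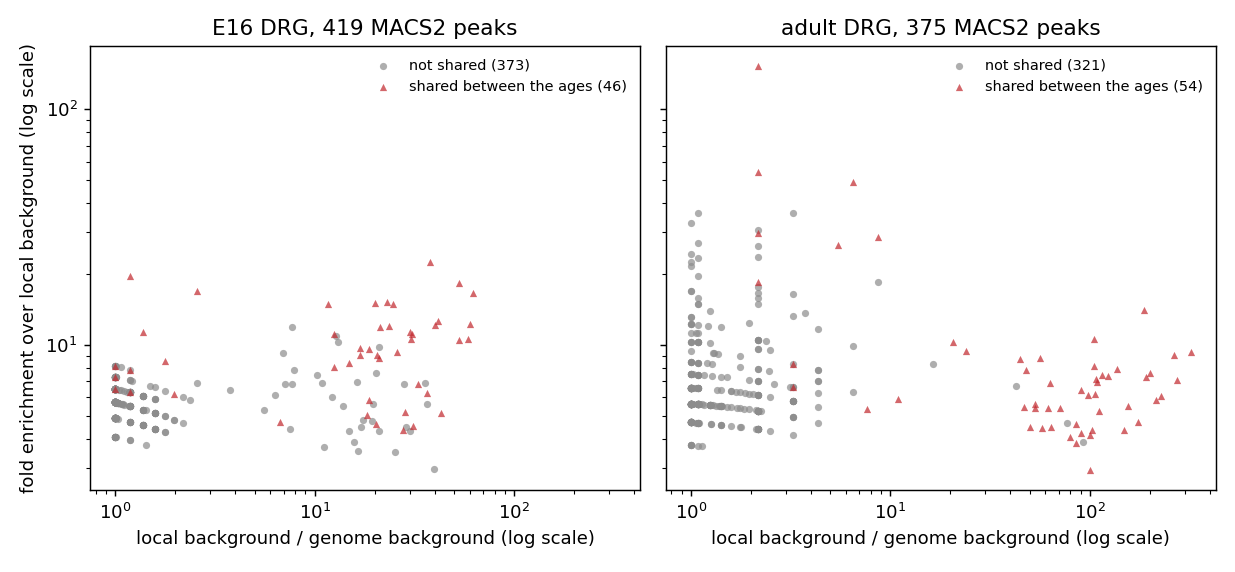
Fold enrichment over local background (vertical, log scale) against local background as a multiple of the genome-wide value (horizontal, log scale) for each E16 peak (left) and adult peak (right); red triangles are peaks shared between the ages and grey circles are not. A local background of 5 times or more was found at 36 of 46 shared and 33 of 373 unshared E16 peaks, and at 48 of 54 and 7 of 321 adult peaks.

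Peaks shared between the ages had a higher median fold, as the caller computes it, within each list than peaks that were not. At E16 the chromosome 2 array nearest to Lrrc4c and the sites near Arid1b, Sulf1 and Rpusd4 led the shared group, whose median fold was 9.47 against 5.69 for unshared peaks. In the adult the sites near Arid1b, Bcl11a and Pou4f1 led it, with medians of 6.74 and 5.64, while unshared adult peaks reached 36.4 near Itga11, where MACS 1.4 did list an E16 peak, and 36.3 inside Ano2. The difference of medians was 3.77 at E16 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give, Benjamini-Hochberg adjusted p over both ages 2e-05, 46 against 373 peaks). In the adult it was 1.11 (permutation p = 0.00547, adjusted p = 0.00547, 54 against 321 peaks). Peaks within an array are not independent of each other. A shared peak also had to be called in the other list, so weak peaks could more easily count as unshared. Without clustered peaks the differences were 2.44 (permutation p = 1e-05, adjusted p = 2e-05, 21 against 349 peaks) and 1.24 (permutation p = 0.0339, adjusted p = 0.0339, 22 against 318 peaks). The fold adds 1 to fragments and to background, so where the background is far below 1 it follows the fragment number. Median fragments were 50 at shared and 6 at unshared E16 peaks, with backgrounds of 20.8 and 1.00 times the genome-wide value. In the adult the fragments were 37.5 and 6, with backgrounds of 84.9 and 1.09 times. The higher fold thus does not show a higher ratio of fragments to background.

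Few peaks lay at the ends of genes, as in random placements. Near the boundary of a protein-coding gene, either end, the highest E16 peak was 153 bp from Cd3d, a subunit of the T-cell receptor complex (chromosome 9, 44987100 to 44987314, fold 8.13). It was followed by summits inside Batf2, Gfi1b and Cibar2 (fold 6.51 each), with Kmo, Trp73, Arpc1b and Tmem259 at 5.65 to 5.69. The highest adult one was 57 bp inside the boundary of Fan1, a DNA repair nuclease gene (chromosome 7, 64345296 to 64345585, fold 12.0). The others were at Fth1, the ferritin heavy chain gene (6.60), Kif20a, a kinesin gene (6.44), Rock1 and Ndst4 (5.64 each) and Lars2 (4.66). The summit at Kif20a lay 21 bp outside that gene and inside Cdc23. There were 12 such peaks at E16 (2.86%) and 6 in the adult (1.60%) for protein-coding genes, and 30 (7.16%, exact 95% interval 4.88 to 10.1) and 23 (6.13%, 3.93 to 9.06) for all annotated genes. Random placements gave means of 3.21% and 3.14% for protein-coding genes and 6.45% and 6.41% for all annotated genes.

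Summits lay inside an annotated gene for 220 E16 peaks (52.5%, 47.6 to 57.4) and 192 adult peaks (51.2%, 46.02 to 56.4). They lay more than 100000 bp from any annotated gene for 25 (5.97%, 3.90 to 8.68) and 17 (4.53%, 2.66 to 7.16). Each of these 6 shares of the MACS2 lists, gene boundaries included, lay within the central 95% of random placements or on its edge. The lowest empirical two-sided p was 0.0619, for adult peaks far from genes (Benjamini-Hochberg adjusted over 6 tests, 0.372). For isolated peaks alone the share inside genes was 56.5% at E16 (random placements 44.1 to 54.3) and 55.0% in the adult (43.5 to 53.8). Against random placements these gave an empirical two-sided p of 0.0140 and 0.0280, with an adjusted p of 0.0839 for each. For protein-coding genes the share of isolated E16 peaks inside genes was 48.6% against 35.9 to 46.5 (permutation of positions, p = 0.00599, adjusted p = 0.0360). In the adult it was 44.7% (permutation of positions, adjusted p = 0.228). In the longer MACS 1.4 lists 5 of the 6 shares left the range of random placements. Inside genes these were 53.3% at E16 (46.8 to 52.03, permutation of positions, adjusted p = 0.0240) and 53.05% in the adult (45.4 to 52.5, adjusted p = 0.0312). Against peaks moved by 50000 to 500000 bp these shares were within range (48.6 to 53.4 and 48.6 to 54.6, permutation adjusted p = 0.0959 and 0.515). Far from genes the shares were 5.95% (6.18 to 8.998) and 5.32% (5.71 to 9.47), with an adjusted empirical p of 0.0312 each against random placements. At gene boundaries E16 had 8.69% (5.16 to 7.67, permutation adjusted p = 0.0240), while the adult had 6.49% (permutation adjusted p = 0.981). The E16 boundary share and the shares far from genes at both ages also left the range of moved peaks. Moved peaks could land before the start of the assembled sequence, where no genes were counted, which raises their share far from genes.

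**Figure D3:**
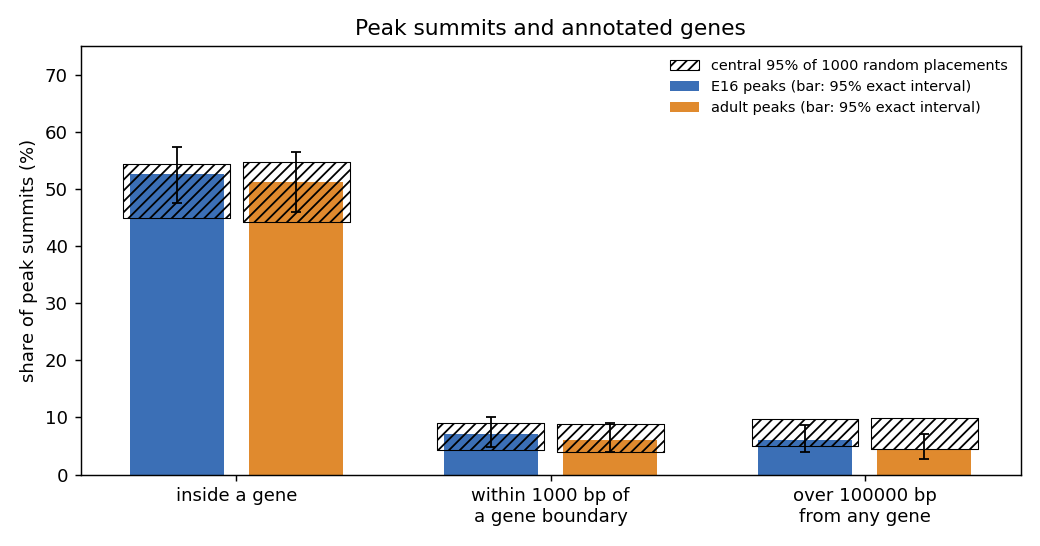
Share of peak summits (percent) inside an annotated gene, within 1000 bp of a gene boundary and more than 100000 bp from any gene, for 419 E16 peaks (blue) and 375 adult peaks (orange), with exact 95% intervals as error bars. Hatched boxes show the central 95% of 1000 random placements on the same chromosomes, and each bar ends within its box or on its edge.

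Among genes of sensory neurons, E16 peaks lay inside Etv1, an ETS transcription factor of proprioceptors (chromosome 12, 38815095 to 38815269, fold 6.51), Cntnap2, a contactin-associated protein of myelinated axons (fold 5.69), and Trpm3, a heat-sensing channel (fold 4.97). Of the genes for axon guidance, the netrin receptor Unc5a (4.88), Epha5 (4.81) and Efnb2 (4.55) had E16 peaks. The adult list had Cntn5 (9.64), the netrin receptor Dcc (5.64) and the SLIT receptor Robo1 (4.70). Genes of synaptic adhesion and receptors had Lrp1b (3 peaks, highest fold 6.71), Lrrtm4 (6.51), Rims2 (5.69) and the glutamate receptor gene Grin2b (5.50) at E16, besides Gabrb1 and Grik4. In the adult they had Ctnna2 (2 peaks, highest fold 6.54) and Lrp1b (5.87). The adult list also had peaks inside Ebf3 (5.33) and Ebf1 (4.67), transcription factors of the EBF family, and Plxnc1, a semaphorin receptor (8.35). All of these summits lay inside the gene bodies, and of these sites the one inside Lrp1b at chromosome 2, 42189511 to 42189685, was shared between the ages.

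No gene list passed the test for an excess of members with a peak. Of 408 genes in 12 lists, 16 had an E16 peak and 8 an adult peak within the gene body or 10000 bp on either side. Synaptic genes numbered 6 of 54 at E16 (mean of random placements 4.46) and 2 of 54 in the adult (3.87), and axon guidance genes 3 of 54 (2.92) and 3 of 54 (2.71). Sensory neuron transcription factors numbered 1 of 32 at E16 (0.480) and 2 of 32 in the adult (0.419), the list with the lowest adult p (0.0609). Nociceptor, thermoreceptor and itch genes numbered 1 of 36 at each age (0.671 and 0.615), mechanoreceptor and proprioceptor genes 1 and 0 of 29 (1.03 and 0.855). Voltage-gated channel genes numbered 3 and 0 of 38 (1.95 and 1.73), with Kcnip1 (5.69), the sodium channel gene Scn8a (5.50) and Cacna1e (5.31) at E16. Lists with no peak at either age were the TALE homeobox genes (11 members), the Hox genes (39), neurotrophic factor receptors and their signalling (21), ribosomal protein and translation genes (40) and markers of fibroblasts, endothelium, immune cells, muscle and blood (30). Random placements also hit few of them, with means of 0.172 to 0.346 members per list and age. Markers of satellite glia and Schwann cells had 1 of 24 at E16, the myelin gene Mbp (5.69), and 0 of 24 in the adult. The mean of random placements was 0.123 at E16, and the empirical one-sided p of 0.119 was the lowest at that age. The empirical one-sided p was under 0.05 for 0 of the 24 list and age tests, and every Benjamini-Hochberg adjusted p over the 24 was 1. With 16 and 8 genes hit, only a large excess in a list would have passed.

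The genes of the proteins that the antibody was labelled as recognising had no MACS2 peak nearby. This absence says little, since random placements hit a mean of 0.346 (E16) and 0.281 (adult) of the 11 TALE homeobox genes. The nearest peak to Meis1 (chromosome 11, 18880428 to 19019651) was 6080 kb away at E16 and 5109 kb away in the adult, and the nearest to Meis2 (chromosome 2, 115861264 to 116067537) 4664 and 3191 kb. For Meis3 (chromosome 7, 16174012 to 16186510) the distances were 2879 and 279 kb. MACS 1.4 listed an adult peak inside Meis2 at 115876131 to 115876651, with a score of 52.61, among the lowest of that list.

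The callers differed mainly in how many weak peaks they listed. Both found the adult sites near Arid1b, Bcl11a and Pou4f1, whereas the MACS 1.4 peak inside Meis2 had no MACS2 counterpart. MACS 1.4 listed 1278 peaks at E16 and 771 in the adult. It overlapped 401 of 419 E16 MACS2 peaks (95.7%, 93.3 to 97.4) and 368 of 375 adult ones (98.1%, 96.2 to 99.2). In return, MACS2 overlapped 382 of 1278 (29.9%, 27.4 to 32.5) and 355 of 771 (46.04%, 42.5 to 49.6). The median MACS 1.4 score was 78.4 for E16 peaks that MACS2 also listed and 64.7 for the others, and 97.49 and 71.7 in the adult. Both callers read the same libraries, so their overlap is no replication. By MACS 1.4 the peaks shared between the ages were 61 at E16 (4.77%) and 62 in the adult (8.04%).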

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

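Alternatives chosen only after the data were seen were the isolated peaks for location, gene lists, callers and fold, and the background of moved peaks. The number of peaks was 1278 (E16) and 771 (adult) in the MACS 1.4 lists, and 271 and 193 for folds of at least the list's median, which is above 50% of each list because folds are tied there. Shared peaks fell to 20 at each age without clustered peaks, because clustered peaks were more often shared (25 of 49 at E16, 32 of 35 in the adult), so that the share fell from 11.0 to 5.41% and from 14.4 to 5.88%. Among adult peaks of at least the median fold they fell to 33, where fewer peaks entered. All counts stayed above the random ones. Asking for 50% overlap of both peaks lowered the share of MACS2 peaks found by MACS 1.4 to 35.8% at E16 and 66.7% in the adult, since MACS 1.4 peaks are wider. Protein-coding genes alone lowered the share inside genes to 44.2% (E16) and 41.3% (adult), and the share at gene boundaries to 2.86% and 1.60%. With all annotated genes, a limit of 5000 bp in place of 1000 bp raised the share at gene boundaries from 7.16 to 26.01% (E16) and from 6.13 to 22.7% (adult). The share more than 100000 bp from a gene lay below the random mean with all genes (5.97% against 7.28 at E16, 4.53% against 7.30 in the adult) and above it with protein-coding genes (30.31% against 26.3, 29.6% against 26.7). The E16 share at gene boundaries turned the other way (7.16% against 6.45, then 2.86% against 3.21). None of these passed.

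The number of gene lists passing was 0 under each of 6 alternatives, but 26 of 144 list results moved to the other side of the random mean, with 0 passing there. With 50000 bp around the gene body these were nociceptor genes (1 at each age), E16 fibroblast, endothelial and immune markers (2), adult Hox genes (1) and adult axon guidance genes (3). With gene ends they were E16 mechanoreceptor genes (1), nociceptor genes (0 at each age), synaptic genes (0 at E16, 2 in the adult), E16 fibroblast, endothelial and immune markers (2), adult Hox genes (1) and adult axon guidance genes (0). In the MACS 1.4 lists they were neurotrophic genes (1 at each age), E16 mechanoreceptor genes (3), and adult TALE (2), Hox (3) and axon guidance genes (5). With −log10 q of at least 3 they were E16 mechanoreceptor (1), nociceptor (0) and axon guidance genes (0). Without clustered peaks there was 1 change, E16 mechanoreceptor genes (1). Against moved peaks there were E16 nociceptor (1) and voltage-gated channel genes (3) and adult axon guidance genes (3).

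Against moved peaks, the share more than 100000 bp from a gene was below the background range at E16 (7.88 to 12.4) and in the adult (6.67 to 11.5), with an adjusted empirical p of 0.00599 for each. For isolated peaks it was within it. The excess of MACS 1.4 summits inside genes was lost against moved peaks, with an adjusted empirical p of 0.0959 at E16 and 0.515 in the adult. Other MACS 1.4 shares stayed outside the range of moved peaks. At E16 the share at gene boundaries was above it (8.69% against 5.48 to 7.98). The share more than 100000 bp from a gene was below it at E16 (5.95% against 6.73 to 9.08) and in the adult (5.32% against 5.71 to 8.69). The same limit of the moved background can bear on these MACS 1.4 shares. The adult share at gene boundaries was within range. Of the 61 strong adult peaks with no E16 MACS2 peak, 59 had none in the E16 MACS 1.4 list either. Motif comparisons, the promoter, exon and intron split, and filters on soft-masked repeats were not run for want of sequence and strand. No paired analysis was possible because each age had 1 library, so that leaving out a replicate was not possible either. Depth limits weak sites most: the median peak rested on 7 fragments at E16 and 6 in the adult.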

Other observations

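Tests of chance for isolated shared peaks, of the sites of low E16 background and of strong adult peaks were chosen only after the results were seen. Those of repeats for clustered and isolated shared peaks and of adult depth for E16 peaks were not, except that the split of the isolated peaks and the other ratios for E16 peaks were weighed afterwards.

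Of 111 adult peaks with at least 10 fragments at the summit, 61 had no E16 MACS2 peak, and 59 of these had none in the E16 MACS 1.4 list either. The exceptions were the peak 69.2 kb from Itga11 and one at chromosome 8, 101146117 to 101146285, whose nearest protein-coding gene was Cdh11. At E16, 35 of 75 peaks with at least 10 fragments had no adult MACS2 peak, 13 of them isolated. The limit of 10 was not scaled for depth, so the counts of the ages are not matched. Scaled by background, the weakest of the 61 adult peaks would hold 35.5 E16 fragments. Of the 61, 27 (44.3%, exact 95% interval 31.5 to 57.6) lay inside a protein-coding gene, against 41.3% of all adult peaks and a mean of 41.0% in random placements. After Ano2 and Lipc, the highest were inside Fam227b (chromosome 2, 126147777 to 126148060, fold 19.6), Zfp821 (chromosome 8, 109707289 to 109707574, fold 18.5), Pdzd2, a PDZ domain gene (fold 15.8), and Lsamp, a cell adhesion gene of the limbic system (chromosome 16, 40785493 to 40785772, fold 14.9). Others were inside Npffr2, a receptor for neuropeptide FF (fold 13.2), the von Willebrand factor gene Vwf (fold 12.4) and Acacb, an acetyl-CoA carboxylase gene (fold 11.7). A peak inside Bcl11a itself (chromosome 11, 24128898 to 24129173, fold 9.48) was among them, apart from the shared site 927 kb away. These genes were named after their values were seen.

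The shared peaks may be a mixture, in which repeats are a candidate explanation for one part and binding of MEIS proteins at both ages remains a hypothesis for another. Chance is argued against, since 20 isolated E16 peaks overlapped an isolated adult peak and random placements gave at most 1. Repeat copies collapsed in the assembly, which draw input reads as well, are consistent with the clustered part, where the lower of the age medians of local background was 24.8 times the genome-wide value. For isolated shared peaks as a whole the median was 6.73 times at E16 and 30.5 times in the adult. Both were above 2, the limit set beforehand for repeats, so that rule was met. By a split weighed afterwards, repeats still cannot be told apart from binding at each site. The E16 median stood between 10 peaks at 2.57 or less and others far above. At the 10 sites of low E16 background, such as those near Arid1b, Bcl11a, Pou4f1 and Sulf1, neither repeats nor carry-over from the adult library can be excluded. Their median adult local background was 3.27 times, against 1.09 at unshared adult peaks, at sites chosen by E16 background. The ratio of E16 to adult fragments differed 4.26-fold where the adult had at least 30. With 1 library per age, repeats and carry-over cannot be told apart from binding.

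The 61 strong adult peaks with no E16 MACS2 peak, such as those near Marcks and inside Ano2, may differ by age or by library. Lower sequencing depth at E16 is argued against, since the E16 background was 3.55 times the adult one. Lower enrichment in the E16 library cannot be told apart from a difference of age, and its test turned on the sites chosen. It used the ratio of fragments at 7 shared sites of low E16 background with at least 10 adult fragments. At that ratio the 61 would have held a median of 3.15 E16 fragments. The number was 2.97 at the median ratio of the 7 and 3.95 without the strongest site. These lie below the 5 at the 5th percentile of called E16 peaks. At the median ratio of all 10 sites it was 5.25, and at the ratio of the 4 sites with 20 to 44 adult fragments 5.73. Neither reached 7, the median of called E16 peaks. Copies of a single amplified fragment cannot be excluded by the width, whose median was 1.72 times the narrowest in the list. Copies read from both ends can also give a wider peak, and the handling of duplicate reads was not given. Age and the success of the immunoprecipitation cannot be told apart with 1 library per age.

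The 373 E16 peaks with no adult peak, such as those inside Etv1, Scn8a and Mbp, may be missing from the adult list for lack of depth, but this cannot be told apart from loss of binding with age, which was not tested. With equal enrichment at both ages the median one would have held 1.69 fragments in the adult library, below the 4 fragments at the 5th percentile of the adult peaks that were called. That assumption did not hold at shared sites of low E16 background: at the ratio of the 7 with at least 10 adult fragments the number would have been 26.6, and at that of the other 3 it would have been 6, the median of called adult peaks. Those sites had to be called at both ages, so they do not settle the ratio for unshared peaks.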
